A study of Homo sapiens with 3 samples.

How the data were processed

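The series holds 3 ChIP-seq libraries of the A2780 cell line, 1 per group: an anti-Flag precipitation of cells with Flag-USP39, an anti-POLR2A precipitation that the series design names as the positive control, and an input from 10% of the genomic DNA. Groups were taken from the antibody given in the labels. No group had a replicate, so no test across samples was made. Per the labels' protocols, precipitated DNA was quantified by fluorometry and electrophoresis and made into sequencing libraries with a commercial kit. Per the submitters' processing notes, Bowtie2 version 2.2.4 and MACS version 1.4.3 were among the tools and the genome build was hg19. The handling of duplicate reads, the total tags per library and the annotation release are not given in the sources used here.

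The values used come from a peak annotation table for each antibody, each headed as that antibody against the input, so each list was called on 1 library and both share 1 input. Per the file headers, the deposited tag counts are whole-number counts of tags in each peak, without normalization. The deposited score is minus 10 times the log10 of the peak caller's p-value, per the file headers, and it is capped at 3100 in the values. The deposited fold enrichment is a linear ratio of the precipitated library to its background, per the file headers. The deposited FDR is in percent, per the file headers, and reached 0.01% for Flag-USP39 and 0.26% for POLR2A. The lowest score was 50 in the Flag-USP39 list and 40 in the POLR2A list, so the authors' lists used p-value thresholds of 1e-05 and 1e-04. The fewest tags in a peak were 3 and 4. The authors' table repeats a peak for each annotated transcript: 20273 lines gave 11565 Flag-USP39 peaks and 27766 lines gave 14027 POLR2A peaks. A peak kept its deposited class from the transcript with the start site nearest to its centre. The deposited promoter class reached 1998 and 1999 bp from a start site in the 2 lists, and the upstream class 19996 and 19997 bp. Scores and fold enrichments are the peaks' own values and were used to describe, rank and filter peaks within a list, and as ranks at overlapping pairs.

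Low values of fold enrichment showed what 1 tag is worth. Over the lowest background, 1 tag gave a fold enrichment of 10.9 in the Flag-USP39 list and 8.31 in the POLR2A list, a background of 0.0919 and 0.120 tags. A median peak of 4 tags therefore carries a wide counting error, and a site with fewer than 3 or 4 tags could not be listed. Depth beyond the tags in peaks is unknown.

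Gene symbols of the tables were matched to a RefSeq gene table of assembly GRCh38.p14, used for names and gene kinds and not for positions. Of the Flag-USP39 transcripts 12266 of 12320 (99.6%) matched, and of the POLR2A transcripts 17016 of 17069 (99.7%). The background for gene tests was the 20056 protein-coding genes of that table, or all 59792 genes for the snRNA and snoRNA lists. Lists of 8 kinds were written by hand and 6 families were taken by name pattern, all before the data were examined. They were the tri-snRNP and spliceosome core, SR and hnRNP regulators, immediate early, heat shock, housekeeping, ovarian cancer, and G2 and mitosis genes, markers of other cell types, and the ribosomal protein, histone, snRNA, snoRNA, olfactory receptor and ZNF families.

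Peaks were compared by overlap of at least 1 bp. The share of Flag-USP39 peaks that met a POLR2A peak was tested against 1000 shuffles of positions within chromosomes, with an alternative that kept the distance to one of 14036 start sites found in the tables. Chromosome ends were the largest positions in the tables. Overlapping pairs were formed 1 to 1, the longest shared stretch taken before others. Promoter shares, gene sets and gene lists were tested by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 28 tests for the lists and a threshold of 0.05. Differences of medians were tested with 100000 permutations and rank correlations with 10000. Shares carry 95% Wilson intervals. The tests treat peaks and genes as independent, which they are not, and describe these lists only. No simulation of the chance overlap that the shared input brings was made, since that needs the reads.

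The genes named were set by rule before the data were examined: the genes of the 10 peaks with the highest fold enrichment and of the 10 with the lowest p-value per antibody on chromosomes 1 to 22 and X, those of the 10 Flag-USP39 peaks with the lowest p-value with and without a POLR2A peak, USP39, POLR2A and HMGA2 whatever their values, and up to 4 members of each list with the lowest p-value per antibody. Other names are said to be chosen after their values were seen, or are members that make up a count. Some of the genes that this rule selects are not reported here.

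The procedures were tested on simulated data. Of 20 lists of 11565 randomly placed peaks, 1 gave p under 0.05 against the POLR2A list, and when 10% of peaks were planted on POLR2A peaks 10.4% were recovered. Of random lists of 30 genes, 3.50% (Flag-USP39) and 7.50% (POLR2A) gave p under 0.05, and of lists drawn at 3 times the odds 38% and 74.5% did, so a moderate enrichment in the Flag-USP39 list would be missed more often than found.

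Alternatives fixed before the data were examined were a stricter p-value of 1e-10, an FDR of at most 5%, a fold enrichment of at least 10, chromosomes 1 to 22 and X alone, promoters within 1 or 3 kb, any annotated peak, another gene background, other definitions of overlap, equal list lengths, another null, and other scores. A p-value threshold of 1e-05 in both lists and a minimum of 10 tags were added after the data were seen. A further 3 gene lists, of keratin genes, keratin-associated protein genes and other epidermis and hair follicle genes, were added at that stage too. All value columns of the tables belonged to the 2 antibodies. Sequence content at peaks was not analysed here, since no hg19 sequence was used. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.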

Results

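Chromatin immunoprecipitation with sequencing was carried out in A2780, a human ovarian cancer cell line, with Flag-tagged USP39. USP39 belongs to the ubiquitin-specific protease family by sequence and is known as a component of the tri-snRNP, the particle that brings the catalytic small nuclear RNAs to the spliceosome. There were 3 libraries: one precipitated with an antibody against the Flag tag, one precipitated with an antibody against POLR2A (the largest subunit of RNA polymerase II, named by the series as the positive control), and an input made from 10% of the genomic DNA. Each group held 1 library, so no value has a replicate error, and every test over peaks or genes describes these 2 peak lists and not the conditions. Each antibody was compared with the same input, so part of any overlap between the lists may come from that library. The Flag-USP39 list held 11565 peaks covering 4742160 bp and the POLR2A list 14027 peaks covering 7203913 bp. Tag counts, fold enrichments over input and p-values per peak are the authors' own, and peak positions are on hg19 throughout.

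The depth behind a single peak was low. The median peak held 4 tags in each list, and 10343 Flag-USP39 peaks (89.4%) held 3 to 5 tags. In the POLR2A list 11550 peaks (82.3%) held 4 or 5 tags. At least 10 tags were found in 338 Flag-USP39 and 593 POLR2A peaks, and at least 20 in 137 and 231. The tags within peaks summed to 62327 for Flag-USP39 and 86228 for POLR2A, and the 10 peaks with the most tags took 13.3% and 9.58% of them. The total number of mapped tags per library is not given in the sources used here. Intervals are 95% Wilson intervals unless another kind is named, and they cover counting error only.

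The first comparison asked where each antibody's peaks lay relative to genes. POLR2A peaks were found at the promoters of histone genes, of splicing regulators such as HNRNPA2B1 and SRSF7, and of HMGA2 and POLR2A itself, whereas few Flag-USP39 peaks lay at promoters. The promoter class, within 2 kb of a transcription start site, held 2509 POLR2A peaks (17.9%, 17.3 to 18.5) and 669 Flag-USP39 peaks (5.78%, 5.37 to 6.23). The odds of a promoter position were 3.55 times higher in the POLR2A list (two-sided Fisher's exact test, p = 8.86e-201). Flag-USP39 peaks lay more often between genes (45.8% against 36%) and in introns (31.0% against 27.6%). Exons held similar shares, 4.38% (4.03 to 4.77) of Flag-USP39 and 4.62% (4.28 to 4.98) of POLR2A peaks. The class up to 20 kb upstream held 13% and 13.9%. Among peaks with 10 or more tags, a threshold chosen after the data were seen, promoters took 19.2% (15.4 to 23.8) of Flag-USP39 and 39.0% (35.1 to 42.9) of POLR2A peaks, and exons 14.2% (10.9 to 18.3) and 7.42% (5.57 to 9.81). The authors' lists used different p-value thresholds, 1e-05 for Flag-USP39 and 1e-04 for POLR2A.

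**Figure D1:**
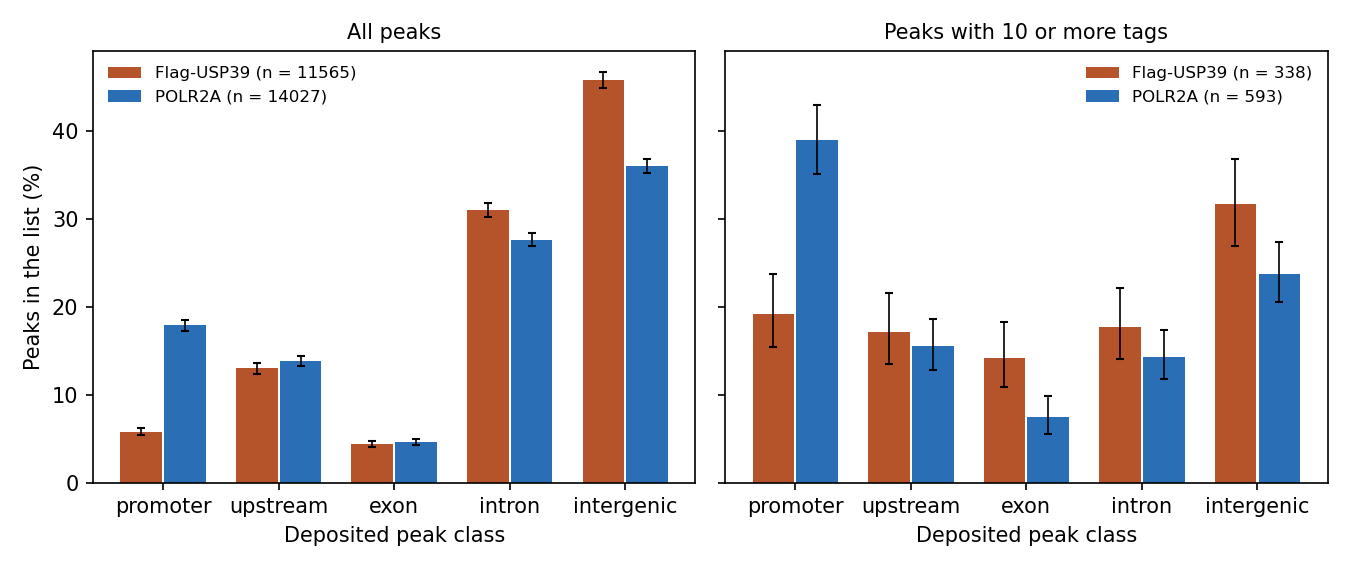
Bars show the percentage of peaks of each list in each deposited class, for all peaks and for peaks with 10 or more tags, and error bars are 95% Wilson intervals. POLR2A exceeds Flag-USP39 in the promoter class in both panels, 17.9% against 5.78% and 39.0% against 19.2%.

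The genes fixed for naming in any case were USP39, HMGA2 and POLR2A. HMGA2, a chromatin architectural factor of embryonic and tumour cells, had 6 POLR2A peaks, 3 of them at its promoter, and no Flag-USP39 peak. The HMGA2 peak with the lowest p-value lay at chr12:66217219–66218963 with 23 tags and a fold enrichment of 58.2. The POLR2A gene carried a POLR2A promoter peak at chr17:7387470–7388336 with 20 tags and a fold enrichment of 86.4, while its best Flag-USP39 peak, at chr17:7392746–7393007, was intronic with 3 tags. USP39 itself had no Flag-USP39 peak and 1 intronic POLR2A peak of 5 tags at chr2:85860788–85861399. A peak of so few tags is near the lower limit of the lists, so the absence of a peak means that none was detectable at this depth.

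Genes with a promoter peak were next counted in gene lists fixed before the data were examined. Of 20056 protein-coding genes, 496 had a Flag-USP39 promoter peak, 2231 a POLR2A promoter peak and 153 both. Chance would place 55.2 genes in both sets (odds ratio 3.75, two-sided Fisher's exact test, p = 1.79e-33). With any annotated peak in place of a promoter peak, 2569 genes were shared against 1674 by chance. In all, 14 gene lists were tested against each antibody's promoter peak genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 28 tests.

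Histone genes, whose products package DNA, gave the highest share of POLR2A promoter peaks of any list. Of 92 histone genes, 61 had one (odds ratio 16.1, adjusted exact p = 7.99e-35) and 14 had a Flag-USP39 promoter peak (odds ratio 7.25, adjusted exact p = 2.01e-07). The tag counts at these promoters were far apart. The linker histone gene HIST1H1D held 40 POLR2A tags at chr6:26233814–26235357 and 4 Flag-USP39 tags. HIST1H1C held 29 POLR2A and 9 Flag-USP39 tags, and HIST1H1B 17 and 7. HIST1H2BD, which encodes a core histone, had 67 POLR2A tags at chr6:26156275–26158934 and no Flag-USP39 peak. The replacement histone gene H3F3B had 14 POLR2A and 8 Flag-USP39 tags. Near-identical histone copies can share reads, so counts at single members of the cluster are uncertain. At 10 or more tags no histone gene had a Flag-USP39 promoter peak, and at a p-value of at most 1e-10 there was 1 (odds ratio 4.66, adjusted exact p = 0.370).

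Genes of the cytosolic ribosome and other abundantly transcribed genes were over-represented in both lists. Ribosomal protein genes had promoter peaks for POLR2A in 40 of 87 cases (odds ratio 6.91, adjusted exact p = 2.40e-15) and for Flag-USP39 in 10 (odds ratio 5.21, adjusted exact p = 1.77e-04). Peaks assigned to the RPS29 promoter held 150 POLR2A and 143 Flag-USP39 tags. The Flag-USP39 one, at chr14:50053244–50053788, had its centre at -382 bp from the start site, upstream of the gene, and whether its tags belong to RPS29 was not tested. RPL15 held 11 POLR2A and 10 Flag-USP39 tags, and RPS20 held 6 and 10. Of 30 housekeeping genes, 18 had a POLR2A promoter peak (odds ratio 12.1, adjusted exact p = 6.87e-10) and 5 a Flag-USP39 one (odds ratio 7.96, adjusted exact p = 0.00197). The best peaks of ACTB, which encodes cytoplasmic actin, held 70 POLR2A and 30 Flag-USP39 tags, and those of ACTG1, a second cytoplasmic actin gene, 36 and 29. The nuclear noncoding RNA gene MALAT1 carried 1661 Flag-USP39 and 1722 POLR2A tags in 1 exon peak each. Another, NEAT1, had 91 POLR2A tags and no Flag-USP39 peak. With any annotated peak counted, the odds ratios of the Flag-USP39 list were 0.834 for ribosomal protein and 0.676 for histone genes, and the housekeeping list no longer passed the threshold (adjusted exact p = 0.0694), nor did it with promoters within 1 kb (adjusted exact p = 0.109).

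Small nucleolar RNA genes, whose RNAs guide modification of other RNAs, had a promoter peak for Flag-USP39 in 32 of 568 cases (odds ratio 4.91, adjusted exact p = 1.32e-11) and for POLR2A in 93 (odds ratio 3.95, adjusted exact p = 8.99e-24). SCARNA10 held 22 Flag-USP39 and 29 POLR2A tags and SNORD17 10 and 12. A peak assigned to both SNORD141A and SNORD141B, at chr9:135894783–135896503, held 168 and 181. The same pair of names was given to another Flag-USP39 promoter peak, at chr6:74226898–74229295 with 49 tags. Whether the tags of either peak belong to these snoRNA genes was not tested. Many such genes lie inside host genes. The background of 59792 genes may hold genes that the annotation behind the peak tables lacks. That would raise the odds ratios of the snoRNA and snRNA lists. Of this background 1.24% had a Flag-USP39 promoter peak, against 2.47% of protein-coding genes. The snoRNA call of Flag-USP39 was kept under 8 of 9 alternatives, a background of the annotated genes alone among them. Of 42 spliceosomal snRNA genes, 5 had a POLR2A promoter peak (odds ratio 2.67, adjusted exact p = 0.0894) and none a Flag-USP39 one. Those of the minor spliceosome held the most POLR2A tags, RNU11 29 at chr1:28974505–28975676, RNU12 26 and RNU4ATAC 23. The best Flag-USP39 peak near any snRNA gene was 7 tags upstream of RNU6-2. The snoRNA odds ratio of the Flag-USP39 list was 1.03 when any annotated peak was counted (adjusted exact p = 0.829). The snRNA list passed the threshold for POLR2A under 4 of 9 alternatives, at a p-value of at most 1e-10 (odds ratio 30.6), against the annotated genes alone (5.66) and under 2 settings added after the data were seen, 10 or more tags (27.2) and a p-value threshold of 1e-05 in both lists (4.37), with adjusted exact p from 9.06e-06 to 0.829 over the 9.

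Splicing factor genes were followed because USP39 is one of them. SR and hnRNP splicing regulators had a POLR2A promoter peak in 18 of 34 cases (odds ratio 9.05, adjusted exact p = 9.66e-09), including HNRNPA2B1 (14 tags, fold enrichment 60.2) and SRSF7 (14 tags, 42.0). Flag-USP39 promoter peaks were found at 3 of the 34 (adjusted exact p = 0.0894). The best Flag-USP39 peak of this list lay in an exon of HNRNPF, at chr10:43882502–43883305, with 11 tags and a fold enrichment of 57.7. Genes of the tri-snRNP and spliceosome core had a POLR2A promoter peak in 10 of 46 cases (odds ratio 2.22, adjusted exact p = 0.0636) and a Flag-USP39 one in 1, CDC5L, with 3 tags. SNRPE, PRPF3 and SRRM2 held 8 POLR2A tags each at their promoters. Neither antibody's promoter peaks passed the threshold for this group in the main test. When any annotated peak was counted, Flag-USP39 peaks were found at 2 of the 46, fewer than among other genes (odds ratio 0.135, adjusted exact p = 0.00160, range 0.00160 to 1 over the alternatives). Gene length and spacing were not allowed for, so this does not show that Flag-USP39 avoids these genes. Against the annotated genes alone POLR2A promoter peaks were over-represented (odds ratio 4.25, adjusted exact p = 0.00724, range 0.00724 to 1). At a p-value of at most 1e-10 the POLR2A call of the SR and hnRNP list ended with 2 of 34 genes left (odds ratio 7.81, adjusted exact p = 0.085).

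Stress and growth-response genes were over-represented among POLR2A promoters. Heat shock protein genes had such a peak in 8 of 18 cases (odds ratio 6.41, adjusted exact p = 0.00101) and immediate early genes in 9 of 25 (odds ratio 4.51, adjusted exact p = 0.00232). DNAJB1, a co-chaperone, held 10 POLR2A tags at its promoter and JUND, a subunit of the AP-1 transcription factor, 15. Flag-USP39 promoter peaks were found at 1 heat shock gene (adjusted exact p = 0.508) and 2 immediate early genes (adjusted exact p = 0.196), 1 of them FOS with 5 tags. Away from promoters, HSPA8, which encodes a constitutive chaperone, had an intronic Flag-USP39 peak of 40 tags at chr11:122928273–122930827 where the POLR2A list had 3 shorter peaks in the gene, the best with 9. HSPA5, its endoplasmic reticulum relative, had exon peaks of 18 Flag-USP39 and 22 POLR2A tags. Both POLR2A calls ended under 3 of 9 alternatives: the p-value threshold of 1e-05 in both lists (odds ratio 3.96, adjusted exact p = 0.0633 for heat shock and 2.64, 0.157 for immediate early genes), a p-value of at most 1e-10 (7.31, 0.291 and 5.17, 0.365) and 10 or more tags (6.68, 0.374 and 4.73, 0.462), the last 2 with 1 gene left in each list.

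Promoter peaks of ovarian cancer genes, mitotic genes and zinc finger genes passed the threshold for neither antibody. Ovarian oncogenes and tumour suppressors had a promoter peak for POLR2A in 7 of 31 cases (adjusted exact p = 0.125) and for Flag-USP39 in 1, NRAS (adjusted exact p = 0.720). They passed for Flag-USP39 when any annotated peak was counted, with 14 of 31 (odds ratio 2.46, adjusted exact p = 0.0467, range 0.0467 to 1 over the alternatives). CCND1, encoding cyclin D1, had exon peaks of 22 Flag-USP39 tags at chr11:69466221–69467838 and 17 POLR2A tags, and CTNNB1, encoding beta-catenin, a POLR2A promoter peak of 9 tags. Of 30 G2 and mitosis genes, 3 had a POLR2A promoter peak (adjusted exact p = 1), MAD2L1 with 5 tags among them, and none a Flag-USP39 one (adjusted exact p = 1). ZNF genes had 54 and 13 of 477 (adjusted exact p = 1 and 0.833). Olfactory receptor genes, silent in most tissues, were under-represented for POLR2A, with 6 of 392 (odds ratio 0.122, adjusted exact p = 1.65e-12), and for Flag-USP39, with 3 (odds ratio 0.300, adjusted exact p = 0.0447). The Flag-USP39 call ended under 4 of 9 alternatives, with promoters within 1 kb (adjusted exact p = 0.356), against the annotated genes alone (odds ratio 0.697, adjusted exact p = 1), and at a p-value of at most 1e-10 or 10 or more tags, where no member had a peak and the POLR2A call ended too (adjusted exact p = 0.187 and 0.149). Markers of blood, liver, muscle and neurons had a POLR2A promoter peak in 1 of 35 cases, MYOD1 with 4 tags (adjusted exact p = 0.256), and no Flag-USP39 one (adjusted exact p = 1). These markers were under-represented for POLR2A when any annotated peak was counted, with 5 of 35 (odds ratio 0.334, adjusted exact p = 0.0467, range 0.0467 to 1 over the alternatives). A test of whether list members made up different shares of the 496 Flag-USP39 and the 2231 POLR2A promoter peak genes passed for none of the 14 lists (adjusted exact p = 1 for each); sets of such unlike size leave room for different counts within a list, such as the 14 and 61 of 92 histone genes.

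**Figure D2:**
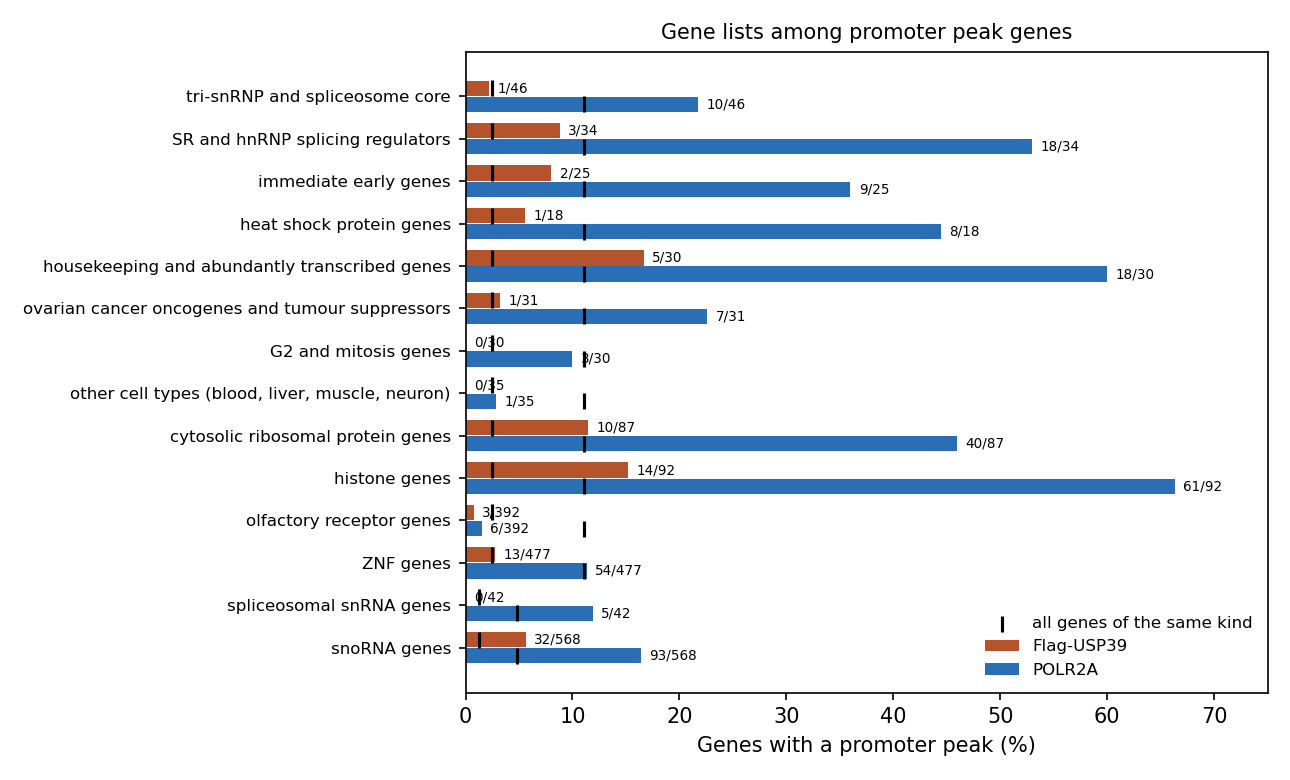
Bars show the percentage of genes in each list with a promoter peak, with counts beside them, and black marks show the percentage among all genes of the same kind. Histone genes stand highest for POLR2A, with 61 of 92, and housekeeping genes highest for Flag-USP39, with 5 of 30.

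The next comparison asked how far Flag-USP39 peaks coincided with POLR2A peaks. Of the 11565 Flag-USP39 peaks, 698 (6.04%, 5.62 to 6.48) overlapped a POLR2A peak by at least 1 bp. Shuffling the Flag-USP39 peaks within their chromosomes gave 0.439% on average and 0.649% at most, and the observed share was 13.8 times that mean (one-sided permutation test, p = 0.001, the smallest that 1000 shuffles can give). Shuffles that kept each peak's distance to a transcription start site gave 1.33% on average, and the observed share was 4.53 times that. In the other direction, 716 POLR2A peaks (5.10%, 4.75 to 5.48) met a Flag-USP39 peak, against 0.363% after shuffling. Exon peaks of the Flag-USP39 list met a POLR2A peak most often, 129 of 507 (25.4%, 21.8 to 29.4), followed by promoter peaks with 135 of 669 (20.2%, 17.3 to 23.4). Intron and intergenic peaks met one in 3.62% and 3.70% of cases.

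The overlap rose steeply with the number of tags. It was 2.03% among Flag-USP39 peaks of 3 to 5 tags, 21.7% at 6 to 9, 83.1% (77.3 to 87.6) at 10 to 19 and 94.2% (88.9 to 97.0) at 20 or more, where 129 of 137 peaks met a POLR2A peak. The tag ranges were chosen after the data were seen. The reverse share depended on the class. Among POLR2A peaks with 20 or more tags, 37 of 74 at promoters (50%, 38.9 to 61.1) and 122 of 157 elsewhere (77.7%, 70.6 to 83.5) met a Flag-USP39 peak (two-sided Fisher's exact test, p = 3.51e-05). With 10 to 19 tags the shares were 22.9% and 59%.

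**Figure D3:**
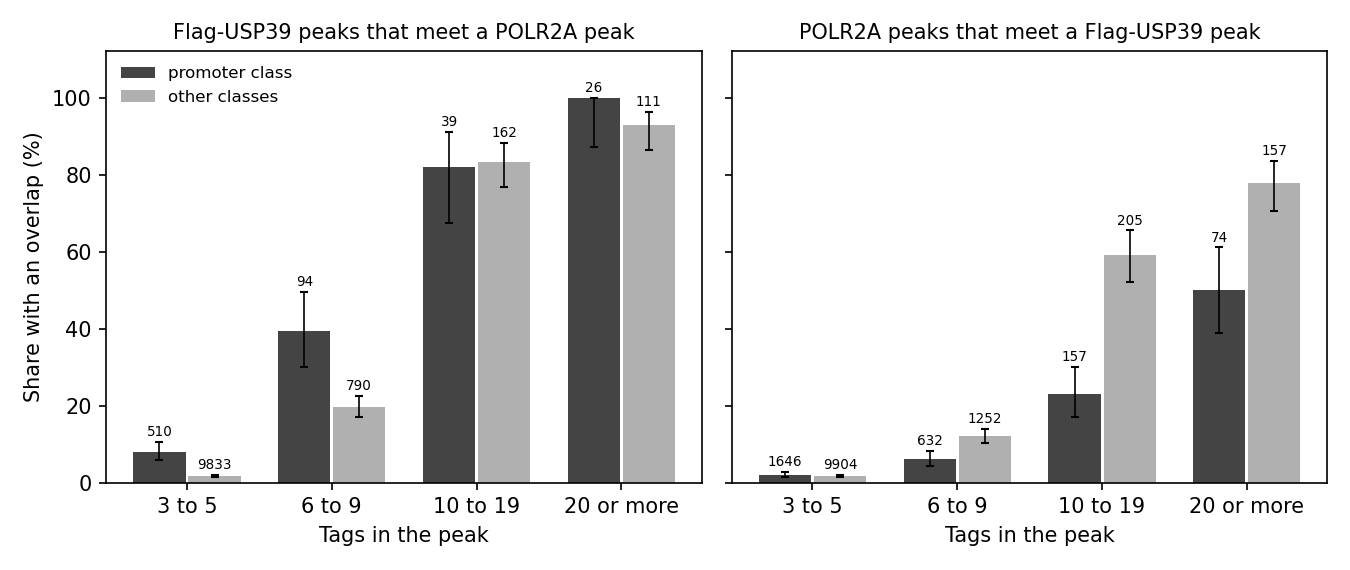
Bars show the percentage of peaks of one list that overlap the other list, by tags per peak and by class, with the number of peaks above each bar and 95% Wilson intervals. Flag-USP39 peaks with 20 or more tags nearly all meet a POLR2A peak, whereas POLR2A promoter peaks of that size meet a Flag-USP39 peak in 50% of cases.

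The peaks with the highest fold enrichment were largely the same loci in both lists. The top Flag-USP39 peak lay upstream of LOC101927914 at chr7:157253871–157254442, with 368 tags, and the POLR2A list had 387 tags there. An intergenic peak was assigned by the authors' annotation to GLRX3 (chr10:132158411–132159040, 204 and 210 tags). An intronic peak of ANAPC7, a subunit gene of the anaphase-promoting complex, held 120 and 124 tags. The promoter of CASC4 held 66 Flag-USP39 tags at chr15:44580549–44580966. The intergenic peak assigned to PLEKHG4B held 1910 and 1938 tags and lay at chr5:9929–11904, near the start of the chromosome. A peak at the start of chromosome 1, assigned to DDX11L1, held 274 and 279. All 10 Flag-USP39 peaks with the lowest p-values met a POLR2A peak.

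Flag-USP39 peaks without a POLR2A peak held a median of 4 tags. By p-value, the leading ones lay in an intron of PLXNA4, a semaphorin co-receptor gene (chr7:131817061–131817348, 11 tags, fold enrichment 119.7), near LINC00564 (10 tags) and near LINC01384 (12 tags). Another lay at the promoter of TCHH, which encodes the hair follicle protein trichohyalin (chr1:152086347–152086659, 9 tags), and 1 in an intron of FLT4, a vascular endothelial growth factor receptor gene (8 tags). Of the 8 unshared peaks with 20 or more tags, those with the most were assigned to ZNF733P (831 tags), MIR3648-1 (124) and LOC101927151 (119), with fold enrichments of 4.60, 4.49 and 8.28. POLR2A peaks without a Flag-USP39 peak included, chosen after their values were seen, 82 tags upstream of GRAP at chr17:18964778–18965928, 67 at HIST1H2BD and 58 at the promoter of C17orf82.

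At 690 overlapping pairs the tag counts of the lists were close. The median ratio of POLR2A to Flag-USP39 tags was 1.03, and 1.02 (interquartile range 0.846 to 1.16) at the 129 pairs with 20 or more Flag-USP39 tags. The authors' fold enrichments correlated across pairs with a Spearman rho of 0.648 and the tags with a rho of 0.739 (two-sided permutation p = 1e-04 for each, the smallest that 10000 permutations can give). Peaks are not independent replicates, and both fold enrichments are taken over the same input, so a positive rho can arise without common binding; the value that this alone would give is not known. Within the Flag-USP39 list, shared peaks had a higher median fold enrichment than unshared ones, 37.7 against 32.7, and a median of 8 against 4 tags (two-sided permutation test over 698 and 10867 peaks, p = 1e-05 for each, the smallest that 100000 resamples can give).

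**Figure D4:**
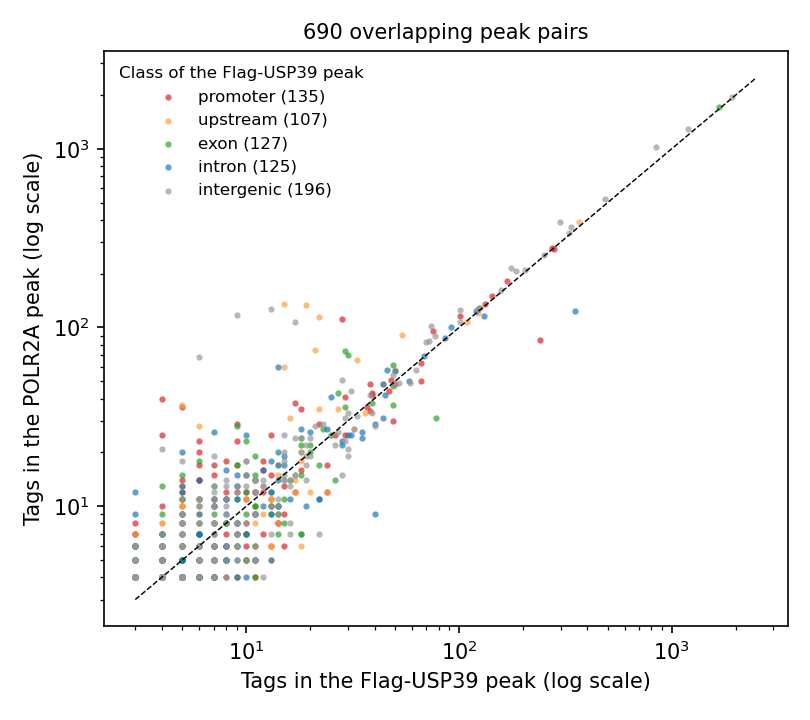
Each point is 1 of 690 overlapping pairs, with tags in the Flag-USP39 peak on the horizontal and tags in the POLR2A peak on the vertical log axis, coloured by the class of the Flag-USP39 peak, and the dashed line marks equal counts. Pairs with many tags lie near the line, with a median ratio of 1.02 at 20 or more Flag-USP39 tags.

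Dense clusters of peaks, chosen after their values were seen, were counted in windows of 500 kb. The window richest in Flag-USP39 peaks held the type II keratin genes of epithelium and hair on chromosome 12 (52500001 to 53000000), with 36 peaks and 415 tags for Flag-USP39 and 36 peaks and 396 tags for POLR2A. The next held the type I keratin genes on chromosome 17 (39500001 to 40000000), with 31 and 36 peaks. KRT85, a hair keratin gene, had exon peaks of 49 Flag-USP39 and 47 POLR2A tags, and KRT5, a keratin gene of basal epidermis, best peaks of 45 and 42. KRT14, the partner of KRT5, had promoter peaks of 37 and 36. The ephrin ligand gene EFNA5 on chromosome 5 (106500001 to 107000000) followed with 24 and 34 peaks. Other windows held many more peaks of the POLR2A list than of the Flag-USP39 list. The HOXB cluster of developmental transcription factor genes on chromosome 17 (46500001 to 47000000) held 32 POLR2A peaks, 17 of them at promoters, and 1 Flag-USP39 peak of 4 tags. The window of TBX2, a T-box transcription factor gene, on chromosome 17 (59000001 to 59500000) held 20 and 1, and a histone cluster on chromosome 6 (26000001 to 26500000) 26 and 6, with 22 and 6 of them at promoters.

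**Figure D5:**
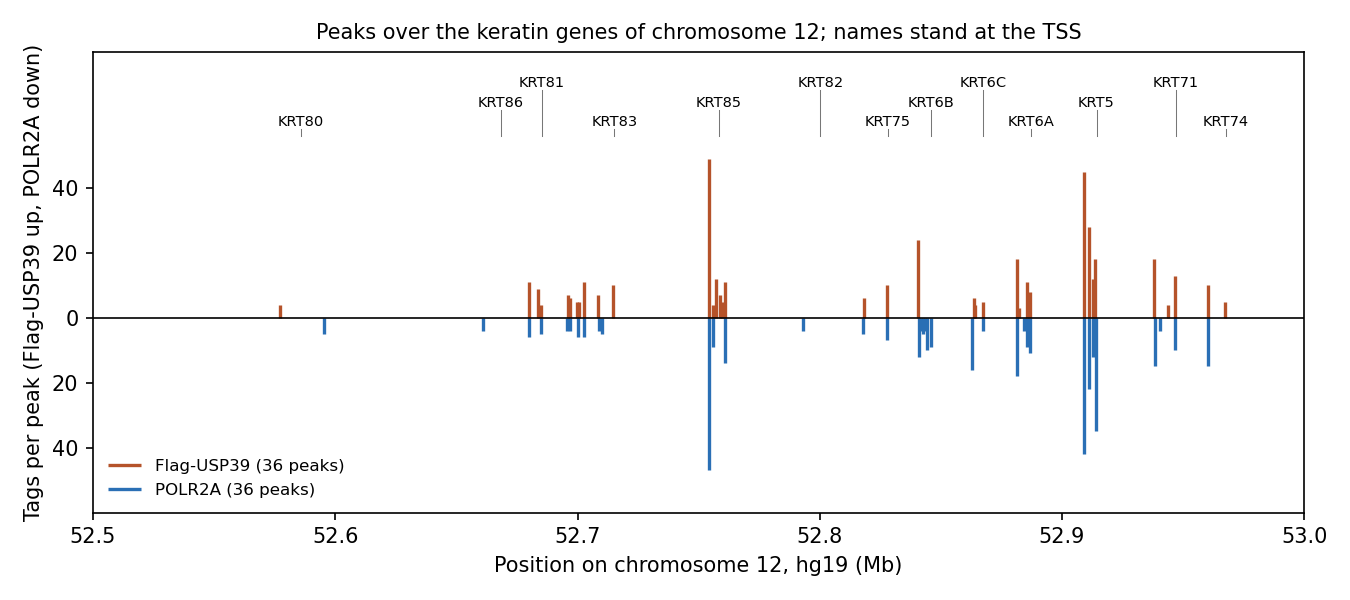
Each vertical bar is a peak at its hg19 position on chromosome 12, in megabases, with its tag count upward for Flag-USP39 and downward for POLR2A, and gene names stand at their transcription start sites. The lists hold 36 peaks each, and the tallest bars of both lie over KRT85 and KRT5.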

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

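The matched p-value threshold, the 10-tag minimum and the tests of the skin and hair lists were chosen only after the data were seen. The share of peaks at promoters differed between the antibodies by a direct test. The odds of a promoter position were 3.55 times higher in the POLR2A list than in the Flag-USP39 list (17.9% against 5.78%, two-sided Fisher's exact test, p = 8.86e-201). With the p-value threshold of 1e-05 in both lists the odds ratio was 4.51, and among peaks with 10 or more tags 2.68. HMGA2, for example, had 3 POLR2A promoter peaks and no Flag-USP39 peak. For none of the 14 lists fixed beforehand did the members' share of the promoter peak genes pass a test of the difference between the antibodies. Histone genes, at 61 of 92 for POLR2A and 14 for Flag-USP39, made up a share of the 2231 and 496 such genes with an odds ratio of 0.968 (adjusted exact p = 1), which does not compare their counts or tags. With 1 library per antibody the difference has no replicate check.

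Skin and hair genes also made up a larger share of the Flag-USP39 than of the POLR2A promoter peak genes by a direct test. The lists were written after 38 of their 220 members had been seen in the same peak tables, so the test is not independent of those peaks. They made up 40 of the 496 Flag-USP39 and 37 of the 2231 POLR2A promoter peak genes (odds ratio POLR2A over Flag-USP39 0.192, adjusted exact p = 5.05e-11). The odds ratio was 0.216 for keratin genes (adjusted exact p = 1.19e-05), 0.139 for keratin-associated protein genes (adjusted exact p = 1.19e-05), 0.283 for the other epidermis and hair follicle genes (adjusted exact p = 0.0159) and 0.216 for the 182 members not seen beforehand (adjusted exact p = 1.56e-05). Keratin genes had a promoter peak in 19 of 55 cases in each list, and the 182 members not seen beforehand in 18 cases in each. The odds ratios set such like counts against promoter peak gene sets of unlike size. They do not show that more of these genes carried a Flag-USP39 peak than a POLR2A peak.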

How the results depend on the processing

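The settings with the p-value threshold of 1e-05 in both lists and with 10 or more tags were chosen only after the data were seen. The share of Flag-USP39 peaks meeting a POLR2A peak stayed above every shuffle under each setting (4.20% to 68.9%, permutation p = 0.001, the smallest possible), and the promoter odds ratio stayed above 1 (2.49 to 5.23), as did the shared against Flag-only difference in fold enrichment. An FDR of at most 5% removed no peak, so its rows could only stay the same. A fold enrichment of at least 10 left 11542 Flag-USP39 and 13958 POLR2A peaks. Chromosomes 1 to 22 and X held 11540 and 14001, so these settings could change little either. The counts of alternatives that follow include all of these rows and overstate how far the results were put to the test. For results that answer a comparison, 63 alternatives kept the direction and call, or a value without a test within its interval or 1.5 times the count, and 19 moved it. For single gene lists 203 left the direction and call, 17 ended a call and 8 made one with the direction kept, and 24 turned the direction. Among the 24, the over-representation called for Flag-USP39 in the main result ended under 1 alternative for ribosomal protein genes and 2 for histone genes. Where a stricter threshold left fewer peaks, the counts follow from its construction; for the rest the cause was not tested.

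At p of at most 1e-10, 381 Flag-USP39 and 520 POLR2A peaks remained, 46.3% of POLR2A peaks met a Flag-USP39 peak, 32 genes had a promoter peak in both lists, and 3 Flag-USP39 and 5 POLR2A gene lists passed (5 and 8 in the main result). At p of at most 1e-05 in both lists, 6914 POLR2A peaks remained and 8.78% met a Flag-USP39 peak. With 10 or more tags, the counts were 338 and 593 peaks, the share 39.6%, the shared genes 24 and the Flag-USP39 lists past the threshold 3. Any annotated peak gave 2569 shared genes and 3 Flag-USP39 lists, and promoters within 1 kb gave 81 genes and 3 lists. The share of POLR2A peaks was 4.08% for an overlap of 50% of the POLR2A peak and 6.09% within 500 bp.

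Gene lists turned direction mostly through a lack of members. The Flag-USP39 odds ratio was 0 for SR and hnRNP, immediate early, heat shock, ovarian cancer and ZNF genes both at p of at most 1e-10 and with 10 or more tags, and 0 for histone genes with 10 or more tags. The POLR2A odds ratio was 0 for the tri-snRNP and spliceosome core under both settings, and for ZNF genes 0 at p of at most 1e-10 and 0.470 with 10 or more tags. With any annotated peak, Flag-USP39 odds ratios were 0.834 for ribosomal protein, 0.676 for histone and 0.936 for ZNF genes, and POLR2A ones 1.34 for G2 and mitosis and 0.873 for ZNF genes. Within 1 kb, Flag-USP39 gave 0 for immediate early and 0.470 for ZNF genes. With all annotated genes as background, the Flag-USP39 odds ratio was 0.892 for ovarian cancer genes and the POLR2A one 1.02 for G2 and mitosis genes. Depth was not varied here; simulated lists of 30 genes at 3 times the odds were detected in 38% of cases among the Flag-USP39 and 74.5% among the POLR2A promoter peak genes.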

Other observations

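The tests of a common background, of spliced transcripts and of skin or hair transcripts, and the bound for sampling noise and its split by class, were chosen only after the results they bear on were seen, as were the gene lists of skin and hair. The genes and regions named here were also chosen after their values were seen.

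Genes of skin and hair outside the keratin clusters carried peaks in both lists, some of close and some of unequal size. TCHH, which encodes trichohyalin of the hair follicle, had 78 Flag-USP39 and 74 POLR2A tags in its best peaks, the Flag-USP39 one at chr1:152078796–152081241. GJA1, a gap junction gene of many tissues, had 124 and 128 at chr6:121767940–121770882 in the Flag-USP39 list, the desmosome-associated gene PERP 49 and 62, and GJB2, a gap junction gene of epidermis and inner ear, 39 and 38. The epithelial cell cycle gene SFN had promoter peaks of 29 and 25 tags. The serpin gene SERPINB5 had 1 exon peak in each list, of 9 and 28 tags, while the desmosome gene PKP1 had a POLR2A peak of 28 tags and no Flag-USP39 peak. The Flag-USP39 list held the most peaks within single genes in EFNA5 (26, with 35 in the POLR2A list), the neuronal adhesion gene NRXN3 (18), the transcription factor gene TRPS1 (16 and 16), the zinc finger gene BNC2 (14 and 11), RNF152 (14 and 9), NBPF20 (13 and 20) and the catenin gene CTNND2 (11). These counts were not adjusted for gene length. NRXN3 spans 1697918 bp, NBPF20 2320934 and CTNND2 932202, against 461286 for BNC2, 294007 for EFNA5, 259516 for TRPS1 and 78001 for RNF152. By chromosome, the ratio of POLR2A to Flag-USP39 peaks was highest on chromosomes 17 (2.02) and 19 (1.68), and lowest on X (0.882).

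The 3 skin and hair lists held 220 genes, 38 of which had been seen in the peak tables before the lists were written and 0 of which stand in another list; their expression in A2780 was not measured here. Of 55 keratin genes, 19 had a promoter peak in each list. Keratin-associated protein genes had a Flag-USP39 promoter peak in 14 of 94 cases, a POLR2A one in 9 and an exon peak in 0. The last count may follow from the promoter class, which takes peaks near a start site whether or not they lie in an exon. Of 71 other epidermis and hair follicle genes, 20 had a Flag-USP39 and 19 a POLR2A exon peak. Housekeeping genes had one in 8 of 30 cases in each list, and G2 and mitosis genes in 0 and 2 of 30. POLR2A promoter peaks without a Flag-USP39 peak were found at 8.18% of the skin and hair genes and 10.8% of all protein-coding genes.

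Strong Flag-USP39 peaks coincided with POLR2A peaks, 94.2% of them at 20 or more tags. USP39 sitting at the promoters that POLR2A occupies is argued against as the whole account of this. Of these 137 peaks, 26 lay at promoters and all 26 met a POLR2A peak, but so did 103 of the 111 elsewhere (92.8%, 86.4 to 96.3). Strong POLR2A promoter peaks met a Flag-USP39 peak less often than others did, 50% (38.9 to 61.1) against 77.7% (70.6 to 83.5). That comparison cannot decide whether USP39 sits at promoters, because the other peaks may hold background common to both precipitations. Background common to both precipitations stays open as a candidate explanation: of 111 Flag-USP39 peaks with 20 or more tags outside promoters, 79.3% (70.8 to 85.8) had POLR2A tags within the 95% binomial range of a single tag ratio of 1.05, an interval that spans the 80% set for it, with the 8 that had no POLR2A peak counted as outside. This replaced a count over the 103 overlapping pairs alone (85.4%, 77.4 to 91.0), which leaves out sites found in 1 list. A single ratio with counting error alone would leave about 95% of peaks within that range, more than either upper bound. So 1 ratio did not hold at every site, although it was fitted to these same pairs. The share of the shared input in the overlap, and USP39 bound together with polymerase away from promoters, were not tested.

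Flag-USP39 peaks of 3 to 5 tags rarely met a POLR2A peak. Of those in exons, 49 of 359 (13.6%, 10.5 to 17.6) met one, over 5 times the mean of 1.18% in shuffles that kept the distance to a start site. Sampling noise placed as in these shuffles is argued against there as the whole cause. The shuffles did not keep peaks within exons, so noise that favours exons in both lists cannot be told apart. For peaks of the other classes sampling noise cannot be told apart: 1.61% (1.38 to 1.88) met one, against a mean of 1.15% and at most 1.44% in shuffles. By class, upstream peaks met one in 2.84% of cases, above their highest shuffle (mean 1.13%, at most 2.15%). The shares were 7.84% for promoter (6.97%, 10.2%), 1.09% for intron (0.920%, 1.52%) and 0.983% for intergenic peaks (0.698%, 1.15%), each below its highest shuffle. One-sided permutation tests over these shuffles, without adjustment, gave p = 0.262 for promoter, 0.152 for intron and 0.015 for intergenic peaks. The intergenic share was 1.41 times its shuffled mean. The excess over the highest shuffle had first been set as the bound, over all classes together (2.03% against 1.6%), but shuffles do not carry the input that both lists share, so 5 times their mean was set in its place. Weak sites of USP39 may be among these peaks, and a second library would be needed to separate them from noise.

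Exon peaks of the Flag-USP39 list met POLR2A peaks more often than intergenic ones, also within strata of equal tags (Mantel-Haenszel odds ratio 4.47, 95% interval 3.23 to 6.18, against 8.89 without strata). More tags per exon peak are therefore argued against as the whole account. Sequence from spliced transcripts in both libraries cannot be told apart: shared exon peaks lay at a median 0.915 of the transcript length from its start, unshared ones of the Flag-USP39 list at 0.869 (two-sided permutation p = 0.113), with 93.0% and 79.6% of them past its midpoint (two-sided Fisher's exact test, p = 3.47e-04, a test added after these shares were seen), and a first comparison with shared intron peaks (0.332) was set aside because exon peaks lie late in transcripts whether shared or not. Transcripts of skin or hair cells may be 1 source. Of 220 such genes, 28 had a Flag-USP39 exon peak, 6.02 times the 2.11% of all protein-coding genes (two-sided Fisher's exact test, p = 2.69e-14). The 182 genes not seen beforehand, a condition added after the 6.02 was known, gave 3.12 times for Flag-USP39 (adjusted exact p = 0.00159) and 2.01 times for POLR2A (adjusted exact p = 0.0679). That condition cannot decide the question. The 38 genes left out had been seen in the peak tables, so leaving them out tends to lower the share by construction. The 94 keratin-associated protein genes, with 0 exon peaks in either list, hold both shares down too. All of their promoter, exon or intron peaks were of the promoter class, which reaches 2 kb from a start site. Their lack of exon peaks may thus follow from the class definition. Abundant transcripts of A2780 itself stay open, with 26.7% of housekeeping genes carrying such a peak, as does transcription of keratin genes in the cultured cells. Tags summed over peaks gave POLR2A to Flag-USP39 ratios of 1.08 for skin and hair genes (95% interval from 10000 resamples of genes 0.961 to 1.23) and 0.940 (0.748 to 1.16) for keratin genes. Keratin-associated protein genes gave 0.904 (0.393 to 1.438). The other epidermis and hair follicle genes gave 1.217 (1.055 to 1.501), an interval above 1 that overlaps those of heat shock and housekeeping genes. Ratios were 1.44 (0.813 to 6.27) for heat shock, 1.63 (1.14 to 2.51) for housekeeping and 2.69 (1.36 to 6.86) for SR and hnRNP genes. For immediate early genes the ratio was 5.53 (1.89 to 89) and for histone genes 21.0 (12.3 to 41.9). These ratios do not decide it, the lists having been called separately at unlike thresholds.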
